A study of Mus musculus with 8 samples.

How the data were processed

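RNA was measured in 8 libraries of the mouse melanoma line YUMM5.2, 4 labelled DMSO and 4 labelled 4-OI, after 20 h of culture. Per the labels' protocols, the molecule was polyA RNA, libraries were made with Illumina TruSeq chemistry and sequenced as paired-end reads on a NextSeq instrument. Each library's group and replicate number were taken from its title, and columns of the tables were matched to libraries by their descriptions.

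Per the submitters' processing notes, the tools named are cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a, RSEM 1.3.3 and MultiQC 1.7, with the genome build GRCm38. Those notes give no role or order. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of antisense or overlapping genes may not be told apart. The authors deposited 3 tables of 55492 genes each, in 3 units: expected counts per gene, as RSEM estimates them, here whole numbers in every cell; TPM, the authors' transcript shares, which take length into account; and FPKM, the authors' values per kilobase and scaled to the number of fragments. Expected counts divide reads that match several genes by a model, so near-identical genes (Gsta1 and Gm3776, the Prl2c family, Ugt1a genes with shared exons, Hspa1a and Hspa1b, Ifit3 and Ifit3b, and ferritin genes with their pseudogenes) are less certain than others. All tests started from the expected counts as deposited, which needed no rounding. Where a symbol stood on more than 1 row (114 symbols on 234 rows, 0.231% of counts), the row with the highest mean count kept the symbol and the others went by their gene identifiers. Positions came from GENCODE mouse release M21, which uses the same build, and 55227 of the identifiers had one there.

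Total counts ranged from 22962963 to 31361677 per library. The depth limits the precision for rare transcripts: 28382 genes had a count of 0 in all 8 libraries. A floor of 3 counts was used as the limit that a count of 0 allows, and floors cover counting error only. Pairs of libraries of 1 group differed by 1.89 to 4.80 times sampling noise (chi-square per degree of freedom), which gave no reason to join libraries, and each counted once.

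The main test was edgeR 4.0.16 in R 4.3.3: filterByExpr on the group (minimum count 10), TMM normalisation, and the two-sided quasi-likelihood F test of 4-OI against DMSO without covariates. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 13531 genes tested. Log2 fold changes are those of the fit, and CPM values are counts divided by each library's total times its TMM factor, on the usual CPM scale. The common biological coefficient of variation was 3.1%. The 33 gene lists were tested with camera of limma 3.58.1 on the same fit, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated for each list and with fry. For NRF2 targets the camera p-value was too small for the software to represent, and only the p with an estimated correlation is printed. Genes below the filter that were of interest beforehand were compared by a two-sided exact permutation test of mean CPM (for these, of library totals without the TMM factor) over all 70 arrangements of the libraries. TPM and FPKM were tested with limma and a trend on log2(value + 1). Figures were drawn with matplotlib 3.10.9.

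The comparison, tests, gene lists and every alternative but the last one below were fixed beforehand. The lists cover NRF2 targets, ferroptosis suppressors and promoters, iron handling, glutathione, the thioredoxin system, ATF4 targets, endoplasmic reticulum chaperones, heat shock, interferon, MHC class I, NF-kB, glycolysis, the tricarboxylic acid cycle, the respiratory chain, cholesterol and fatty acid synthesis, fatty acid oxidation, melanocyte, mesenchymal and matrix genes, DNA replication, mitosis, MAPK output, hypoxia, lysosomes, p53 targets, mitochondrial and ribosomal transcripts, and markers of immune cells, fibroblasts, endothelium and keratinocytes. They came from general knowledge, and some share members: 22 members of the NRF2 list also stand in other lists. Counts adjusted over the list alone are given where they differ from those over all genes. Named genes followed a rule: the 16 focal genes, the 10 highest and 10 lowest called genes at 5 CPM or more with complete separation of the groups, leaving out predicted and clone names, and up to 4 members per list by size of change. Other members are named to spell out counts of 5 or fewer, or as further examples, and were chosen after their values were seen. Some members that the rule names are not reported here.

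The procedure was tested on simulated counts for the 13531 genes. Of 50 genes per size, it recovered 72% at 1.2-fold, 70% at 1.5-fold, 86% at 2-fold and 100% at 4-fold, and at 5 CPM or more 35 of 38, 30 of 30, 32 of 32 and 30 of 30. False calls made up 9 of 173 calls. With no gene changed, 1 gene was called and 0 of 33 lists. Simulated genes were drawn independently of each other, so the 0 of 33 does not show how often lists of correlated genes are called falsely.

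Alternatives were other scalings (RLE, upper quartile, library totals), DESeq2 1.42.0, limma-voom, other filters, TPM and FPKM with other pseudocounts, the replicate number as a block, a stricter threshold, a test against 2-fold (glmTreat), removal of mitochondrial genes or of shared list members, and each library left out in turn. A correction for GC content and transcript length (loess offsets per library) was added after the data had been seen. Reads were not analysed here.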

Results

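Gene expression was measured by RNA sequencing in 8 libraries of YUMM5.2, a mouse melanoma line. Cultures received either the solvent DMSO (4 libraries) or 4-OI (4 libraries) for 20 h. The labels describe 4-OI as a permeable form of itaconate. In this field the abbreviation stands for 4-octyl itaconate, an ester of itaconate, which is a metabolite that activated macrophages make with the enzyme ACOD1. The dose is not given in the sources used here. Total counts were 26433287, 24224397, 22962963 and 31361677 in the DMSO libraries and 25664999, 27959773, 29910876 and 31185027 in the 4-OI libraries. The title of the series names the itaconate transporter SLC13A3 and resistance to ferroptosis, a form of cell death driven by iron-dependent lipid peroxidation. The single comparison asks which transcripts differ between tumour cells given 4-OI and those given DMSO, and how ferroptosis genes fare among them. No library received itaconate itself, so effects of 4-OI cannot be equated with those of itaconate.

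Treatment with 4-OI was followed by a large rise of the antioxidant genes that the transcription factor NRF2 controls, with 33 of 35 measured targets higher and a median log2 fold change of 1.26. Genes of fatty acid oxidation and cytosolic heat shock proteins were also higher. In the opposite direction, 27 of 28 measured interferon response genes were lower, with a median log2 fold change of -1.09, together with chemokines and other NF-kB targets. Mitotic genes and endoplasmic reticulum chaperones were lower by smaller amounts. Of 13531 genes tested with edgeR's quasi-likelihood test, 2607 were higher and 2646 lower at a Benjamini-Hochberg adjusted p under 0.05.

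Among those calls, 134 genes were higher by at least 2-fold and 102 were lower by at least 2-fold. Most calls were small: 4588 of the called genes (87.3%) changed by less than 1.5-fold, and their median absolute log2 fold change was 0.21. In 2356 genes every 4-OI library lay above every DMSO library, and in 2429 genes every 4-OI library lay below. Together these are 35.4% of the tested genes, where chance gives 2.86%. A correction for GC content and transcript length in each library, added after the data had been seen, gave 2197 higher and 3415 lower, a share of higher calls of 39.1% against 49.6% without it. Scaling by library totals tipped the balance the other way, with 3020 higher and 2323 lower (56.5% higher). No source used here says that the libraries came from separate cultures, although the labels speak of separate experiments, so p-values measure only the spread between these samples, which may be technical.

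**Figure D1:**
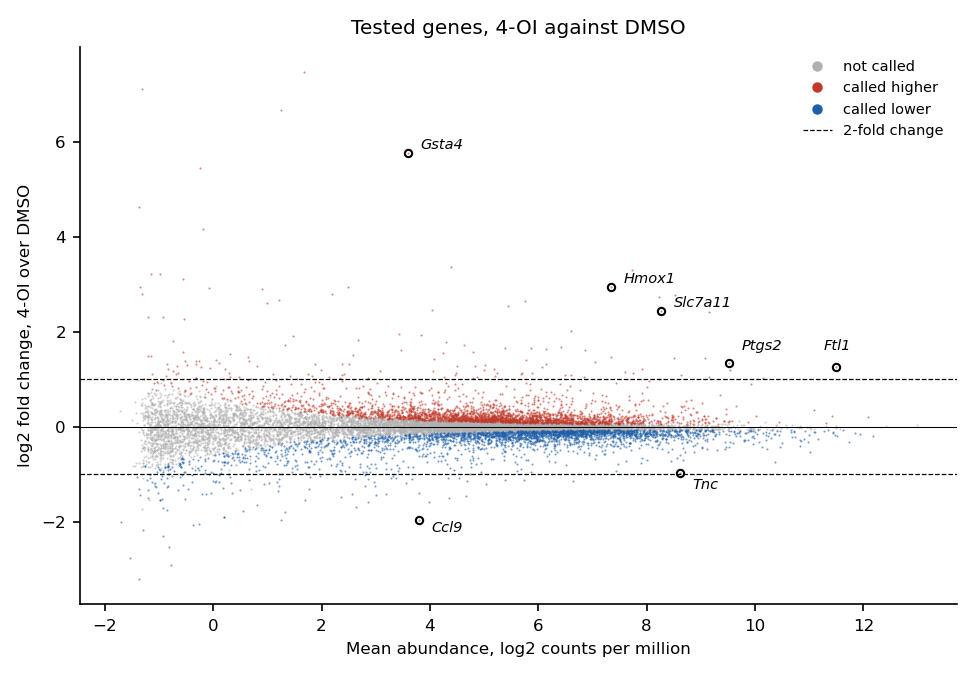
Each point is 1 of the 13531 tested genes. The horizontal axis is mean abundance as log2 CPM (counts scaled to a common library size) and the vertical axis the log2 fold change of 4-OI over DMSO. Red and blue mark genes called higher (2607) and lower (2646) by edgeR, grey the rest, and dashed lines a 2-fold change. Slc7a11, at 2.43, and Hmox1, at 2.95, stand far above most genes of their abundance.

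Of 16 genes of the itaconate, NRF2 and ferroptosis axis chosen before the data were examined, 14 could be tested, of which 10 were higher, 1 was lower and 3 were not called. Adjusted over the list alone, 11 were higher, with Aifm2 added, and 1 was lower. Slc7a11, the cystine importer that feeds glutathione synthesis (GRCm38 chromosome 3, 49892526 to 50443614), had 95.9 ± 2.45 CPM (SD, n = 4) with DMSO and 516.6 ± 11.1 (SD, n = 4) with 4-OI. Its log2 fold change was 2.43 with a standard error of 0.03 (edgeR adjusted p = 5.17e-23). Hmox1, the heme-degrading oxygenase (chromosome 8, 75093621 to 75100589), went from 36.8 ± 2.58 to 284 ± 2.15 CPM, a log2 fold change of 2.95 (edgeR adjusted p = 1.54e-22). Nqo1, a quinone reductase and classical NRF2 target (chromosome 8, 107388225 to 107403206), went from 77.8 ± 1.94 to 515 ± 6.42 CPM, a log2 fold change of 2.73 (edgeR adjusted p = 4.11e-24). Gclm and Gclc, the modifier and catalytic subunits of glutamate-cysteine ligase, had log2 fold changes of 2.41 and 1.08. Txnrd1, cytosolic thioredoxin reductase, rose by 1.45 on the log2 scale, with every 4-OI library above every DMSO library.

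The ferritin genes that store iron were among the most abundant of these transcripts: Ftl1 rose from 1703 ± 47.1 to 4090 ± 77.4 CPM, and Fth1 from 750 ± 23.4 to 1519 ± 13.2 CPM (SD, n = 4). Both have processed pseudogenes that can share their reads, so their levels are less certain than those of single-copy genes. Acsl4, which loads polyunsaturated fatty acids into lipids and promotes ferroptosis, was higher by a log2 fold change of 0.22. Keap1, the negative regulator of NRF2, was higher by 0.18. Nfe2l2, the gene of NRF2 itself, fell by 0.13 on the log2 scale (edgeR adjusted p = 0.000261), and all 4 libraries with 4-OI lay below all 4 with DMSO. Gpx4, the peroxidase that repairs lipid peroxides, had 327 ± 11.9 and 335 ± 5.39 CPM (SD, n = 4), with a log2 fold change of 0.03 (edgeR adjusted p = 0.327). Aifm2, which encodes the ferroptosis suppressor FSP1, had a log2 fold change of 0.14 (edgeR adjusted p = 0.0926), and without DMSO replicate 3 the adjusted p was 0.0452, without 4-OI replicate 4 it was 0.0401. Tfrc, the transferrin receptor, had a log2 fold change of -0.03 (edgeR adjusted p = 0.422), which became -0.08 with the GC and length correction (adjusted p = 0.00543).

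Slc13a3, the transporter in the series title (chromosome 2, 165405028 to 165473230), was close to the limit of detection, with counts of 0, 5, 5 and 3 in the DMSO libraries and 2, 1, 0 and 0 in the 4-OI libraries. In the 3 libraries with a count of 0, that count allows up to 0.1135, 0.1003 and 0.0962 CPM at 3 counts. A two-sided exact permutation test of its CPM gave p = 0.171, and no difference was detectable at this depth. Acod1, which encodes the itaconate-producing enzyme, had counts of 23, 6, 16 and 18 with DMSO and of 1, 5, 3 and 1 with 4-OI, or 0.597 ± 0.263 and 0.0875 ± 0.0682 CPM (SD, n = 4). The two-sided exact permutation p was 0.0286, the smallest that 4 against 4 libraries allow, and 0.0571 after Benjamini-Hochberg adjustment over these 2 genes. The limits at 3 counts cover counting error only, while the SDs and permutation tests also hold the spread between libraries.

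**Figure D2:**
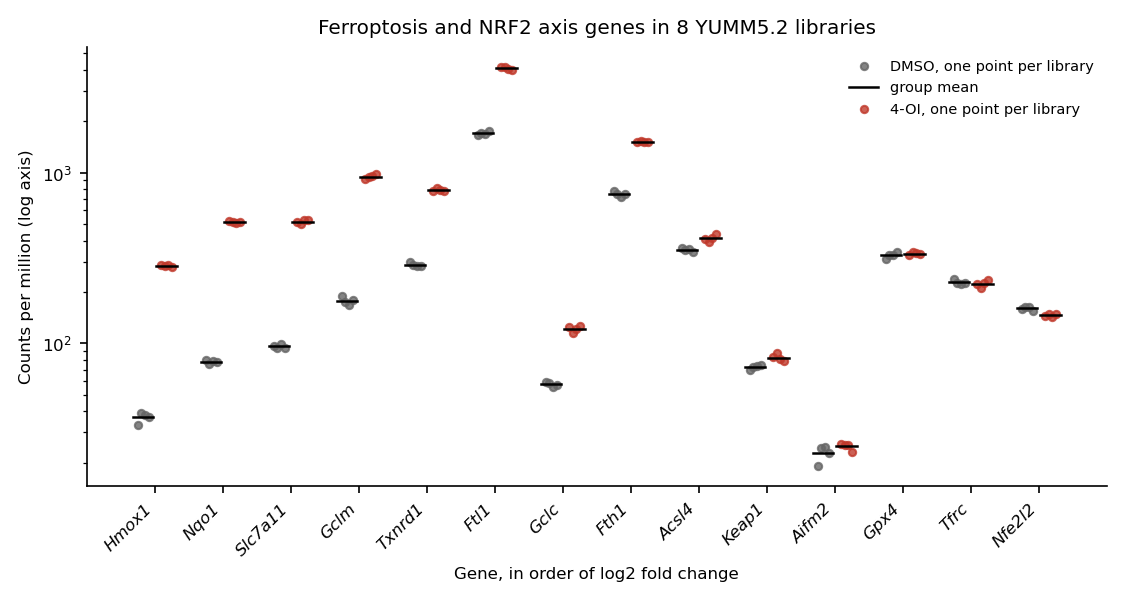
CPM on a log axis for the 14 tested genes of the ferroptosis and NRF2 axis, ordered by log2 fold change. Grey points are the 4 DMSO libraries, red points the 4 4-OI libraries and black bars group means. The groups of Slc7a11 lie near 95.9 and 517, while those of Gpx4, near 327 and 335, overlap.

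The NRF2 target list fixed beforehand had 33 of its 35 tested members higher. The lower member was Ugdh (-0.15) and the member not called was Akr1b8 (-0.03). Gsta4, a glutathione S-transferase that conjugates lipid aldehydes, went from 0.419 ± 0.163 to 22.7 ± 0.705 CPM (SD, n = 4). Srxn1, sulfiredoxin, rose from 92.8 ± 0.578 to 641 ± 16.5 CPM, a log2 fold change of 2.79. Blvrb, a biliverdin reductase, had a log2 fold change of 2.54. Gsta1 rose from counts of 0 to 2 per DMSO library to 128 to 217 per 4-OI library, but shares most of its sequence with Gm3776, so its level is uncertain. The list was called higher by camera, and its adjusted p with an estimated correlation was 1.72e-05.

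Among genes of glutathione synthesis and use, 13 of 20 tested members were higher and the other 7, with Gpx4 and Gpx1 among them, were not called; 14 were higher adjusted over the list alone. Gclm went from 178 ± 8.85 to 948 ± 24.2 CPM (SD, n = 4) and Gstm1, a glutathione S-transferase, from 56.4 ± 2.19 to 173 ± 4.02 CPM. The list was called higher (camera adjusted p = 2.04e-39, and adjusted p = 0.000113 with an estimated correlation). In the thioredoxin and NADPH supply list, 13 of 25 members were higher, 10 were not called, and Rpia (-0.15) and Prdx5 (-0.10) were lower, with 3 lower adjusted over the list alone. The call of Rpia ended without DMSO replicate 1, 3 or 4 or 4-OI replicate 2 or 3 (edgeR adjusted p = 0.0548 to 0.13), and that of Prdx5 without DMSO replicate 2, 3 or 4 or 4-OI replicate 1 or 3 (0.0564 to 0.0921). With scaling by library totals neither was called (0.0539 and 0.0548). Taldo1, transaldolase of the pentose phosphate pathway, had a log2 fold change of 1.47. This list was called higher (camera adjusted p = 8.68e-45, and adjusted p = 9.73e-05 with an estimated correlation), but without the members it shares with the NRF2 list the camera adjusted p was 0.284, and without all members of several lists 0.985.

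Of the known ferroptosis suppressors, 12 of 23 tested members were higher, 8 were not called, and Hspa5 (-0.41), Mboat1 (-0.20) and Nfe2l2 (-0.13) were lower (5 lower with the GC and length correction). Slc40a1, the iron exporter ferroportin, had the largest log2 fold change of the list, 2.94, at under 1 CPM in both groups. Camera called the list higher (adjusted p = 4.89e-22, and adjusted p = 0.000821 with an estimated correlation). Without the NRF2 list's members, 8 of 19 were higher, with a median log2 fold change of 0.03 and a camera adjusted p of 0.00471. Without every member that stands in more than 1 list, the call ended (mean log2 fold change 0.08, camera adjusted p = 0.506). Ferroptosis promoters gave 7 higher of 18 tested, led by Acsf2 (0.53) and Bach1 (0.38), the latter a repressor of NRF2 target genes. Hmgb1 (-0.16) and Vdac2 (-0.12) were lower, and camera did not call the list (camera adjusted p = 0.29). Fry, which does not compare a list with other genes, called it higher (fry adjusted p = 0.00161). With the GC and length correction 6 promoters were higher and 5 lower. In the iron handling list 6 of 20 members were higher, with Hmox1, Ftl1 and Hfe (1.05) among them, while Iscu (-0.15), Pcbp2 (-0.14), Slc39a14 (-0.13) and Aco1 (-0.11) were lower (7 lower with the GC and length correction). Its median log2 fold change was -0.03 and its mean 0.45, so the median differs in sign from the mean and from the camera call, which was higher (adjusted p = 9.54e-11, and adjusted p = 0.00165 with an estimated correlation). Leaving out Hmox1, Ftl1 and Fth1, which are also NRF2 targets, ended the call (camera adjusted p = 0.993).

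Stress responses moved apart. Heat shock genes were higher in 17 of 21 members, with Hspb1 going from 17.9 ± 1.38 to 28.1 ± 1.18 CPM (SD, n = 4), Cryab at a log2 fold change of 0.64 and Hspb8 at 0.57. The members not called were Hspa1a (0.14), Hspe1 (0.03), Hsf1 (-0.03) and Hspa4 (0.02), and reads of Hspa1a cannot be cleanly told from those of its near-identical neighbour Hspa1b. The list was called higher (camera adjusted p = 2.49e-11, and adjusted p = 0.0454 with an estimated correlation). Endoplasmic reticulum chaperones were lower in 17 of 20 members. Hspa5, the main chaperone of that compartment, went from 2064 ± 44.6 to 1558 ± 58.1 CPM (SD, n = 4), while Sdf2l1 (-0.43) and Creld2 (-0.42) fell by similar factors. Sel1l, Dnajb9 and Derl1 were not called. Camera called this list lower (adjusted p = 2.17e-09, and adjusted p = 0.0454 with an estimated correlation).

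Targets of ATF4 in the integrated stress response went both ways, with 11 of 31 tested members higher and 8 lower (9 adjusted over the list alone). Slc7a11 and its partner Slc3a2 (0.49) were at the top, and Ddit4 (-0.44) and Slc7a5 (-0.33) at the bottom. Camera called the list higher (adjusted p = 0.00729), a call lost with an estimated correlation (adjusted p = 0.661) and without members of several lists (camera adjusted p = 0.882). Lysosome and autophagy genes were higher in 19 of 28 members (21 adjusted over the list alone), led by Sqstm1, the autophagy receptor p62 (0.90), Gabarapl1 (0.65) and Ctsd (0.45), while Gpnmb (-0.09) was lower. The camera adjusted p was 2.82e-07, and with an estimated correlation the adjusted p was 0.125.

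Interferon response genes were lower as a group. Ifit1 fell from 16.6 ± 1.21 to 7.32 ± 0.577 CPM (SD, n = 4), Oasl2 from 11.9 ± 0.841 to 4.39 ± 0.438 CPM and Parp14 from 7.64 ± 0.804 to 2.75 ± 0.314 CPM. Only Oasl1 (-0.17) of the 28 tested members was not called. The list was called lower (camera adjusted p = 5.62e-17, and adjusted p = 0.00449 with an estimated correlation). These were low-abundance transcripts, with 14 of the 28 at 5 CPM or more on average, and Ifit3 and Ifit3b can share reads. Genes of MHC class I antigen presentation were lower in 9 of 10 tested members, with H2-T23 at -0.48, Erap1 at -0.46 and Psmb10 at -0.39, and Tap2 (0.09) was not called. Camera called that list lower (adjusted p = 0.00032), and with an estimated correlation the adjusted p was 0.0501. Reads of H2 genes can be shared among family members.

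In the list of NF-kB and inflammatory mediators, 17 of 21 tested members were lower (18 adjusted over the list alone). The chemokine genes Cxcl10 and Ccl7 fell from 30.3 ± 1.54 to 10.8 ± 0.172 CPM and from 46.4 ± 1.91 to 20.0 ± 1.79 CPM (SD, n = 4). Cxcl1, Cd274 and Nfkbiz were not called. Ptgs2, which encodes the prostaglandin-forming enzyme COX-2, was the member that rose, from 413 ± 11.05 to 1054 ± 59.1 CPM, a log2 fold change of 1.35 (edgeR adjusted p = 3.84e-17). The list was called lower (camera adjusted p = 1.07e-17, and adjusted p = 0.000606 with an estimated correlation).

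Metabolic genes changed selectively. Targets of the lipid sensors PPAR and enzymes of fatty acid oxidation were higher in 17 of 20 tested members. Angptl4, an inhibitor of lipoprotein lipase, went from 14.6 ± 0.638 to 90.9 ± 1.42 CPM (SD, n = 4). Cpt1a, which carries out the rate-limiting step of mitochondrial fatty acid import, went from 34.1 ± 0.907 to 106.0 ± 3.00 CPM, and Pdk4, which restrains pyruvate dehydrogenase, from 5.32 ± 0.671 to 16.3 ± 0.330 CPM. Hadhb (-0.12) was lower, and Eci1 (0.03) and Hadha (-0.02) were not called. Camera called the list higher (adjusted p = 1.06e-30, and adjusted p = 0.000855 with an estimated correlation). Glycolysis genes were lower in 14 of 19 members, among them the lactate exporter Slc16a3 (-0.67), Pdk1 (-0.51) and Pfkl (-0.46), while Pfkm (0.13) was higher. The camera adjusted p was 1.65e-09, but 0.108 as an adjusted p with an estimated correlation. Hypoxia response genes were lower in 14 of 18 members (15 adjusted over the list alone), with Ankrd37 (-1.41), Bnip3 (-0.67) and Ndrg1 (-0.56) in front and Vegfa (0.13) higher. Their camera adjusted p was 1.18e-09, and with an estimated correlation the adjusted p was 0.156.

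Other metabolic lists were not called by camera. In the tricarboxylic acid cycle, 4 of 22 members were higher and 7 lower, the median log2 fold change was -0.02, and the mean was 0.06 with the camera direction upward (adjusted p = 0.557). This balance depends on the scaling, with 4 higher and 2 lower for library totals and 4 higher and 9 lower with the GC and length correction. Pcx, pyruvate carboxylase, was the outstanding riser, from 19.9 ± 1.12 to 62.9 ± 2.40 CPM (SD, n = 4). Suclg1 (0.10) and Ogdh (0.06) were also higher, and the largest falls were those of Fh1 (-0.14) and Idh3a (-0.12). In the nuclear-encoded respiratory chain, 23 of 28 members were not called, and Uqcrh (-0.12), Atp5a1 (-0.10), Uqcrfs1 (-0.09) and Atp5b (-0.08) were lower. Of these 4, Atp5a1 alone was called when adjusted over the list. The call of Uqcrh ended without DMSO replicate 2 or 4 or 4-OI replicate 1, 2 or 3 (edgeR adjusted p = 0.0614 to 0.158), and that of Uqcrfs1 without DMSO replicate 2 or 4 or 4-OI replicate 1 (0.0554 to 0.0707). The number lower also depends on the scaling: 1 for library totals, 7 for upper quartiles and 9 with the GC and length correction. The camera adjusted p was 0.557. Cholesterol synthesis split into 6 higher, among them Hsd17b7 (0.28), and 7 lower, among them Mvk (-0.31), of 25 (camera adjusted p = 0.977), or 5 and 11 with the GC and length correction. Fatty acid synthesis had Acsl3 (0.23), Acly (0.11), Elovl6 (0.09) and Fads1 (0.08) higher and Srebf1 (-0.20) and Acaca (-0.07) lower, the last not called without any 1 of 6 libraries (DMSO replicates 1, 2 and 4 and 4-OI replicates 1, 3 and 4; edgeR adjusted p = 0.056 to 0.114), of 14 members (camera adjusted p = 0.659). For library totals 6 of these members were higher and 1 lower.

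Extracellular matrix genes were lower in 17 of 26 members (18 adjusted over the list alone) and the other 9 were not called. Postn, periostin, fell from 13.4 ± 0.729 to 5.02 ± 0.136 CPM (SD, n = 4), Col1a1 from 20.3 ± 0.840 to 7.75 ± 0.572 CPM and Col6a2 from 9.42 ± 1.00 to 4.67 ± 0.511 CPM. Camera called the list lower (adjusted p = 2.99e-18), a call lost with an estimated correlation (adjusted p = 0.0685). Fibroblast markers, given below, were lower as well (4 of 6 tested, median log2 fold change -0.35). In the list of mesenchymal and undifferentiated melanoma genes, 11 of 18 were lower, with Tnc, tenascin C, going from 517 ± 7.57 to 265 ± 7.35 CPM and Loxl2 at -0.85. Fosl1 (0.43), Nt5e (0.21) and Nes (0.20) were among those higher. This call too was lost with an estimated correlation (camera adjusted p = 0.000244, then adjusted p = 0.0685). Melanocyte differentiation genes were mostly below the filter on low counts, with 3 of 19 tested. Mitf, the lineage transcription factor, was higher (0.64), Mlph was lower (-0.77) and Myo5a (0.06) was not called, though it joined the higher genes adjusted over the list alone (2 higher) and without DMSO replicate 3 (edgeR adjusted p = 0.0474) or with library totals (0.0236). The camera adjusted p of this list was 0.514.

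Proliferation genes were lower by small amounts. Of 35 mitosis genes 34 were lower, and all 35 adjusted over the list alone. The median log2 fold change was -0.24. Mki67 fell from 409 ± 8.78 to 295 ± 6.25 CPM (SD, n = 4), and Ube2c and Kif11 had log2 fold changes of -0.41 and -0.40. Camera called the list lower (adjusted p = 1.33e-16, and adjusted p = 0.00836 with an estimated correlation). DNA replication genes were lower in 24 of 33 members, among them E2f8 (-0.47) and Ung (-0.47). Adjusted over the list alone, Pcna (0.05) was also called, as higher. Camera called the list lower (adjusted p = 0.000951), but the adjusted p with an estimated correlation was 0.246. MAPK output genes split evenly: Dusp4 (0.79), Fosl1 (0.43), Phlda1 (0.33), Ier3 (0.18) and Etv1 (0.11) were higher, and Epha4 (-0.70), Ccnd1 (-0.35), Epha2 (-0.16), Dusp6 (-0.11) and Spred2 (-0.10) were lower, of 19 members (camera adjusted p = 0.508). Genes known as p53 targets gave 10 higher, such as Tnfrsf10b (0.37) and Sesn1 (0.29), and 6 lower (7 adjusted over the list alone), such as Bbc3 (-0.45) and Pmaip1 (-0.36), of 22 (camera adjusted p = 0.556).

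Markers of other cell types were mostly below the filter on low counts. Of 15 immune cell markers, Cd14 (16.1 ± 0.587 and 16.9 ± 0.336 CPM; SD, n = 4) and Cd68 passed the filter on low counts, and neither was called. The list's median and mean were -0.05 while its camera direction was upward (adjusted p = 0.985). The endothelial list had Egfl7 as its only tested member of 10, with a log2 fold change of 0.24 (edgeR adjusted p = 0.0654), called adjusted over the list alone and without DMSO replicate 4 (adjusted p = 0.0124) or with library totals (0.049), and a camera adjusted p of 0.698. Keratinocyte markers had 2 tested of 10, Sfn (0.39, edgeR adjusted p = 0.0469, but 0.0558 to 0.123 without DMSO replicate 1, 3 or 4 or 4-OI replicate 1 or 2 and 0.0519 with upper-quartile scaling) and Krt10 (0.10, not called), with a camera adjusted p of 0.698. Fibroblast markers had 6 tested of 11, of which Dcn (-1.39), Pdgfrb (-0.48), Col3a1 (-0.45) and Cd34 (-0.25) were lower, Pdgfra (0.10) was higher and Fbln1 (-0.05) was not called. Camera called them lower (adjusted p = 0.00184), but the adjusted p with an estimated correlation was 0.203. Mitochondrially encoded transcripts took 3.04% ± 0.0353 of the counts with DMSO and 3.02% ± 0.108 with 4-OI (SD, n = 4). Of their 13 members 6 were lower, led by mt-Nd4l (-0.25), mt-Nd6 (-0.17) and mt-Nd1 (-0.15), and 7 were not called (camera adjusted p = 0.29, or 0.0325 without 4-OI replicate 4). Cytosolic ribosomal protein genes gave 6 lower of 30, among them Rps19, Rpl13 and Rps9 at -0.10, -0.10 and -0.09, with 24 not called. The number lower depends on the scaling: 2 for library totals and 14 with the GC and length correction. Without DMSO replicate 2 or 4 or 4-OI replicate 1 or 3 Rps19 was not called (edgeR adjusted p = 0.0515 to 0.146). The list was not called either (camera adjusted p = 0.308).

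**Figure D3:**
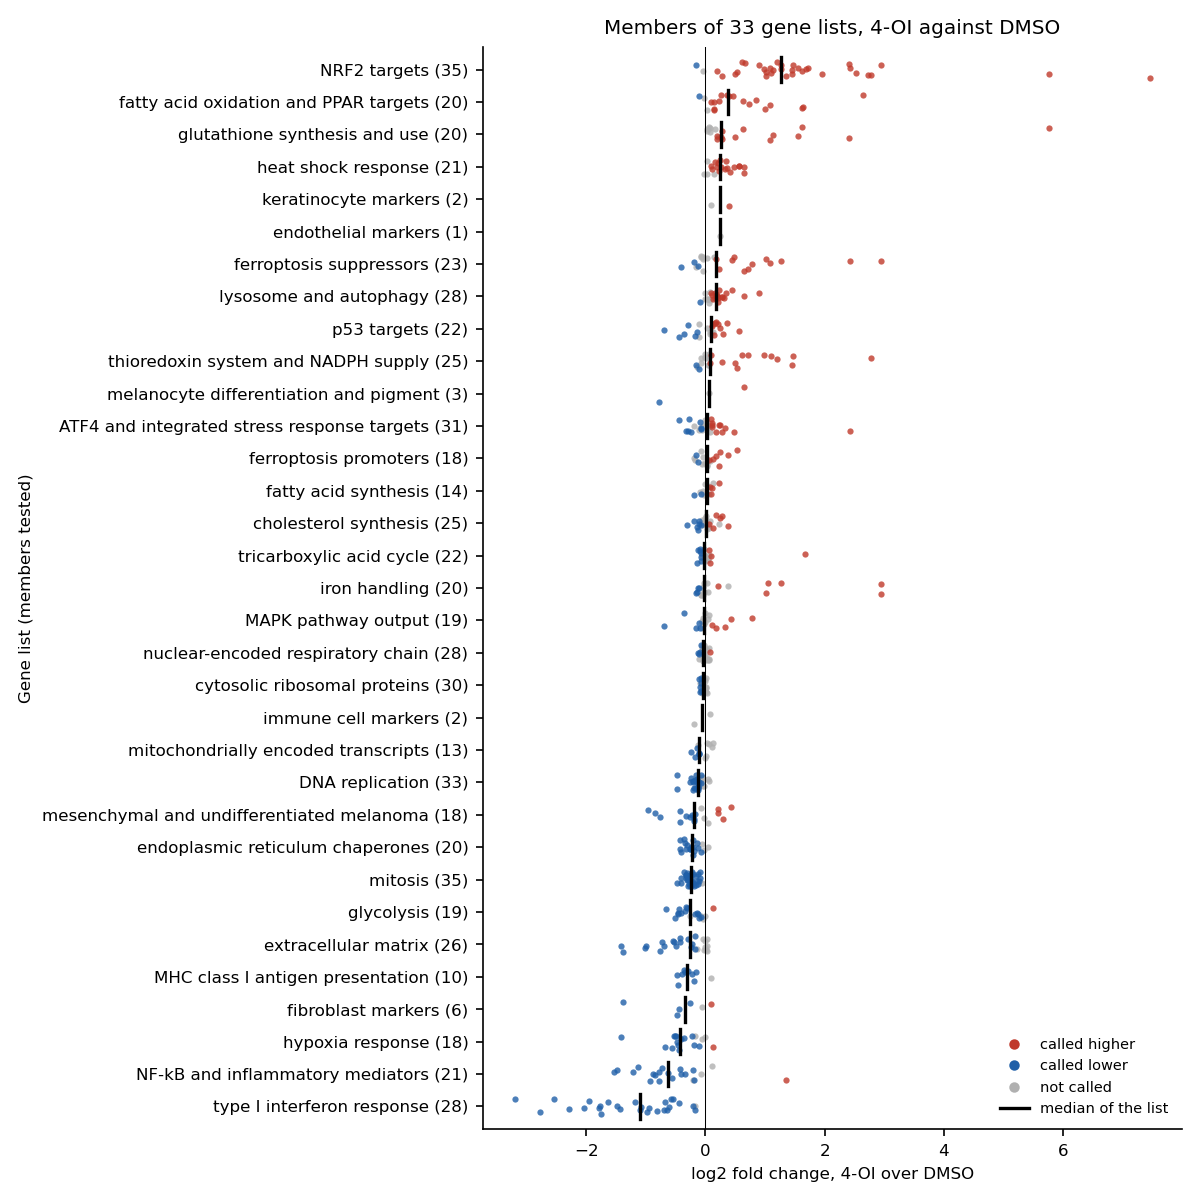
Log2 fold change of 4-OI over DMSO (horizontal axis) for the tested members of 33 gene lists, sorted by median, with the number tested in brackets. Red points were called higher, blue points lower and grey points neither, and black bars are medians. NRF2 targets have the highest median, 1.26, and interferon response genes the lowest, -1.09. The point near 7.5 is Gsta1, whose fitted value rests on counts of 0 to 2 per DMSO library.

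By size of change, the highest genes among those at 5 CPM or more whose groups separated completely were Gsta4, Ampd3 (3.37), Aldh3a1 (3.31), Calr3 (2.95), Hmox1, Srxn1, Nqo1, Angptl4, Blvrb and Prl2c2 (2.47). Aldh3a1, an aldehyde dehydrogenase, went from 38.9 ± 0.903 to 385 ± 9.53 CPM and Ampd3, an AMP deaminase, from 3.59 ± 0.459 to 36.9 ± 2.12 CPM (SD, n = 4). Prl2c2 belongs to a family of near-identical prolactin-like genes, so its level is uncertain. The lowest were Ccl9 (-1.95), Edn1 (-1.70), Gbp3 (-1.57), Cxcl10, Parp14, Gvin1 (-1.47), Oasl2, Postn, Ankrd37 and Col1a1. The chemokine gene Ccl9 fell from 22.5 ± 0.768 to 5.82 ± 0.420 CPM, and Edn1, which encodes the vasoconstrictor endothelin 1, from 9.71 ± 0.530 to 2.98 ± 0.238 CPM. Gvin1 has close relatives in its family and is likewise uncertain.

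Of the 33 lists, camera called 20, 9 higher and 11 lower, and 11 of the 33 were called with an estimated correlation. Fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 25, and 29 for change in either direction. The lists that fry called and camera did not were all called higher. They were ferroptosis promoters (fry adjusted p = 0.00161), the tricarboxylic acid cycle (0.00103), MAPK output (0.00347), melanocyte genes (0.00726) and p53 targets (0.0239). Library structure followed the treatment: the first principal component held 46.5% of the variance and separated the groups, the second held 11.3%, and correlations of log2 CPM were 0.993 to 0.996 within groups and 0.988 to 0.990 between them. In the other deposited units, tested by another method, limma on log2(TPM + 1) called 3380 genes and on log2(FPKM + 1) 3423, of which 3196 and 3217 were also called from the counts, all with the same sign. On those scales fold changes of low genes are understated. Across genes, which are not independent replicates, their fold changes correlated with those of the counts at r = 0.844 and 0.825, and at 0.964 and 0.961 over the 10067 genes at 5 CPM or more.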

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

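In the paragraphs that follow, the tests of the interferon genes and of the small changes were chosen after the results had been seen, while the tests of shared sequence in glutathione S-transferase genes were written before theirs.

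Of 242 sets of 4 libraries, 10 had 1 library whose gap to the nearest other was large against the whole range. That is no more than the share of about 5% that chance alone gives. In the DMSO group, replicate 1 stood apart for Acaca (155.1 CPM, the others 149.6 to 150.5), Parp14 (6.44 CPM, the others 7.99 to 8.12), Prdx5 (79.5 CPM, the others 87.4 to 88.9) and Slc16a3 (41.2 CPM, the others 45.3 to 45.6), and replicate 4 for Egfl7 (5.29 CPM, the others 4.13 to 4.24). In the 4-OI group, replicate 4 stood apart for Acly (457 CPM, the others 467 to 469), Cd14 (16.4 CPM, the others 17.0 to 17.1), Cxcl10 (11.03 CPM, the others 10.65 to 10.71) and Tnc (254 CPM, the others 268 to 269), and replicate 2 for Hspb1 (26.3 CPM, the others 28.5 to 28.9). Except for Cd14 and Egfl7, which were not called, every one of these genes was called in the comparison of the groups. The sets came from the named genes and from measures of the libraries. Most named genes were chosen among called genes, so these calls carry no further meaning.

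The fall of 27 of 28 interferon response genes is open to a trivial reading, since immune cells in the DMSO cultures might carry such transcripts. That reading needs immune transcripts in proportion. All 15 immune markers summed to 18.3 CPM with DMSO and 19.0 CPM with 4-OI, most of it Cd14. Their sum did not fall, while the interferon list lost 113.8 CPM. Cd14 and Cd68 were left out of a second sum after the data had been seen. The other 13, with Tyrobp, Lyz2 and Fcer1g among them, summed to 0.44 CPM with DMSO and 0.30 CPM with 4-OI. Which cells express Cd14 and Cd68 was not tested. Low counts argue no better: the 14 members at 5 CPM or more had a median log2 fold change of -0.68 and 13 of them were called lower. With the GC and length correction the list's median was -1.12, and camera called it lower (adjusted p = 8.22e-15). Only immune cells were weighed as another source. Of 6 fibroblast markers tested, 4 were lower and 1 higher (median log2 fold change -0.35). Lower interferon signalling in the tumour cells themselves, under 4-OI, remains a hypothesis found and tested on the same data. Ifnb1 had 0 counts over the 8 libraries, so its own transcript cannot say more at this depth.

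Small changes in a large share of genes (38.8% called, 87.3% of the calls under 1.5-fold) could come from a bias of the libraries. GC content and length do not account for all of it, since 4811 of these genes were called again with the same sign after that correction. A shift in composition by a few strongly changed genes is also disfavoured: RLE, upper-quartile and total-count scaling moved the median log2 fold change of all genes by at most 0.018. What cannot be told apart is a broad response from replicates that vary less than independent cultures would. The libraries of a group differed by at least 1.89 times sampling noise, a value that both readings allow. The labels speak of separate experiments but do not say whether cultures were separate.

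Alpha-class glutathione S-transferase genes rose from near 0, and here sequence shared between copies may set the level of some of them. Of the 75-base windows in Gsta1 transcripts, 84.7% also occur in another gene, chiefly Gm3776 (69.3%), so the mean counts of Gsta1 (0.75 with DMSO and 170.5 with 4-OI) and Gm3776 (1 and 125.5) may be reads of 1 gene divided between both. Of the windows of Gsta4, 0% occur elsewhere, and its mean counts went from 10.75 to 654.75, so shared sequence does not account for its rise. Division of reads between Gsta1 and Gm3776 would blur which of them rose, and could make both appear to rise where only 1 did. A response of this class to 4-OI is a hypothesis that rests here on Gsta4 and, with the copy left open, on Gsta1 and Gm3776.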

How the results depend on the processing

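All alternatives were chosen beforehand except the correction for GC content and length, which was chosen after the data had been seen. Of 27 alternatives chosen beforehand, 6 (adjusted p under 0.01, the test against 2-fold, and 4 on lists) gave no values of single genes. Over the other 21 and that correction, 2464 of 2571 values of named genes kept their direction and their side of the threshold, and 22 of 117 named genes changed a call or direction at least once. Genes called both in the main test and in an alternative had the same sign in the 22 alternatives where this was counted. The RLE, upper-quartile and total-count scalings, DESeq2 and limma-voom called 4333 (DESeq2, with 13136 adjusted p values given as NA) to 5343 genes. With TPM and FPKM the unit, the test (limma with a trend) and the pseudocount changed together. On log2(TPM + 1) genes lower numbered 1620, and at least 2-fold 68 were higher and 22 lower. With log2(TPM + 0.1), 1615 were lower and 65 lower by 2-fold, and with log2(FPKM + 1), 1535 were lower, 63 higher by 2-fold and 18 lower by 2-fold. On log2(TPM + 1) without a filter, 1362 were higher and 1284 lower, 69 and 23 by 2-fold. A pseudocount of 1 shrinks low genes by its construction. Its size hardly changed the number called, 3380 genes with log2(TPM + 1) and 3365 with log2(TPM + 0.1). What else made the calls fewer was not tested. Acaca, lower in the counts, was at 0.0210 with log2(TPM + 1) filtered or not, 0.0215 with log2(TPM + 0.1) and 0.0288 with log2(FPKM + 1), the cause of which was not tested. Without a filter on low counts 217 genes were higher and 211 lower by 2-fold, and with at least 1 CPM in 4 libraries 60 were lower by 2-fold, because these settings test more or fewer low genes. A test against 2-fold itself, which asks more, called 68 higher and 27 lower. An estimated correlation called 11 lists in place of 20. That option also tests with fewer degrees of freedom, and the cause of the fewer calls was not tested. The iron handling list changed its camera direction from up to down, not called, without members of several lists (mean log2 fold change 0.0724, camera adjusted p = 0.924) and without NRF2 targets (0.224, camera adjusted p = 0.993). Hmox1, Ftl1 and Fth1, which are among its 6 higher members, are left out in both. Leaving out 1 library gave 2249 to 2522 higher, 2369 to 2666 lower, 135 to 149 and 114 to 136 by 2-fold, and 20 to 21 lists. Whether the replicate numbers pair the libraries stayed unclear. Deviations of same-numbered libraries correlated at 0.07, 0.07, -0.01 and -0.02, and those of differently numbered libraries at -0.12 to 0.04. Of 8 libraries, 4 correlated best with their own number. With the replicate block 2526 genes were higher, 2618 lower, 134 and 106 by 2-fold, and 20 lists were called. Depth limits rare transcripts such as Slc13a3 and Acod1.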

Other observations

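The gene families described first were chosen after their values had been seen, and each had the same direction under TMM, RLE, upper-quartile and total-count scaling and the GC and length correction. No enrichment test was run on these families. Of 12 aldehyde dehydrogenases 8 were higher with 4-OI, with Aldh5a1 at a log2 fold change of 0.77 and Aldh2 at 0.55 beside Aldh3a1, while Aldh4a1 (-0.27) and Aldh16a1 (-0.20) were lower. All 3 tested UDP-glucuronosyltransferases, which share exons, were higher, with a median of 1.06. So were 6 of 8 aldo-keto reductases (5 under upper-quartile scaling or the GC and length correction) and 3 of 5 ABCC transporters. Some of these genes stand in the lists of the report as well, such as Abcc1, Abcc4 and Akr1b8 among NRF2 targets and Aldh1l2 among ATF4 targets. Of 6 prostaglandin synthesis genes 4 were higher and Ptgs1 and Ptges2 were not called. Beside Ptgs2, Pla2g4a, the phospholipase that frees arachidonic acid, went from 119 to 266 CPM (log2 fold change 1.16), and Ptges (0.30) and Ptges3 (0.21) were also higher.

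Among secreted and vascular factors, 8 of 12 CC and CXC chemokines were lower (9 with the GC and length correction), with Ccl2 falling from 138 to 63.0 CPM and Cxcl12 from 73.5 to 33.9 CPM. Of 12 vascular growth factor genes 8 were lower, such as Apln (-0.95), Pdgfb (-0.94) and Pgf (-0.81), and Vegfa and Fgf2 (0.19) were higher, of which 1 stayed called under the GC and length correction. Contractile genes were lower in 9 of 10 members (10 with that correction), with Acta2 going from 294 to 186 CPM and Cav1 from 503 to 309 CPM. Of 11 ADAMTS proteases 7 were lower, such as Adamts9 (-0.85), and 1 was higher. Fibroblast markers were lower as well (4 of 6 tested, median -0.35, with Dcn at -1.39). Interferon-inducible GTPases were lower in 9 of 10 members, with a median of -1.17, and 7 of 10 genes of interferon receptors and their signalling were lower (8 with that correction) while Tyk2 (0.21) was higher.

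Whether other groupings of the libraries give as much was tested over all 35 splits into 4 and 4, as fixed beforehand, with edgeR for genes. The split results by kind and with an estimated correlation were added afterwards. For each of the 4 gene counts (2607 higher, 2646 lower, 134 and 102 by at least 2-fold), 1 of 35 splits, the real one, gave a value as large, and the highest of the other splits was 0. That share is the smallest that 35 splits allow. Every other split mixes the groups, so a difference between the groups becomes spread within its sets of 4 and lowers its calls. The 0 of the other splits is therefore no rate of chance calls, and it does not decide whether a chance labelling could give such counts. If the libraries of a group are not separate cultures, a chance difference between cultures could give the same result. For the same reason the test does not say what made the groups differ, since every other split mixes them. For the number of lists called by camera, 5 of 35 splits gave at least the real 20, and the highest of the others was 21, so that number alone does not exclude chance. Splits that put 3 libraries of a group with 1 of the other called 17 to 21 lists, and 4 of them called at least 20. By design these splits keep part of the treatment contrast, so they do not stand for chance alone. The 18 splits with 2 of each called 0 to 3. There that contrast cancels between the sets of 4 but stays as spread within them. The 0 to 3 is therefore no rate of chance calls either. With an estimated correlation the real split called 11 lists and every other split 0. That correlation is estimated from the spread within the sets of 4, which in every other split holds the treatment contrast. That 0 therefore does not show what chance gives.

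Medians of the log2 fold change over the 20 chromosomes with at least 100 tested genes lay between -0.01 (chromosome 3) and 0.03 (chromosome 13).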
